A study of Mus musculus with 24 samples.

How the data were processed

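RNA was measured in 20 libraries of mouse macrophages, 12 from bone marrow cultures (BMDM) and 8 from cells sorted out of melanomas (TAM). The 4 libraries of immunoprecipitated 5-hydroxymethylcytosine in the series of 24 samples have 1 library per group and were not analysed here. Values were deposited by the authors as FPKM (fragments scaled by transcript length and library total) for each gene and library. Per the submitters' processing notes, reads were aligned with TopHat to the mm9 build of the mouse genome and quantified with Cuffdiff, and the other libraries went through Bowtie2 and MACS. No versions, gene annotation or filters are stated, and it is not stated whether Cuffdiff also scaled the libraries. The BMDM table names its unit. The TAM table does not, and FPKM was taken from the processing notes, from its identical gene rows and from its decimal values with unequal totals. Per the labels, the BMDM libraries were made after depletion of ribosomal RNA and the TAM libraries from polyadenylated RNA, so their levels were not compared directly.

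Both tables list 23309 gene models by symbol, of which 23173 matched a symbol or synonym of the reference. Among the symbols, 27 read as dates and were kept as deposited. For 2 symbols listed more than 1 time the entry with the higher mean was used. FPKM values hold no counts, so absolute depth and counting intervals are unknown. The step between the lowest values of genes with a mean under 0.15 FPKM gives the depth relative to the first library of each table, 0.86 to 1.35 in BMDM and 0.22 to 1.0 in TAM. Total FPKM was 365140 to 557218 in BMDM and 338014 to 464833 in TAM, and 7511 to 9089 and 8501 to 11138 genes were listed at 0.

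Values were analysed as log2(FPKM + 1) with R 4.3.3 and limma 3.58.1. A gene was tested when it reached 1 FPKM in at least as many libraries as the smallest group holds (2 in BMDM, 4 in TAM). Members of gene lists that were tested are called measured below, and the others can have values that are low or confined to fewer libraries. The 12 BMDM libraries were fitted together as 6 groups with 6 residual degrees of freedom (10.3 with the prior), and the 8 TAM libraries as 2 groups (6, and 8.5 with the prior), with empirical Bayes moderation and an intensity trend. Every p for a gene comes from limma and was adjusted by Benjamini and Hochberg's method over all genes tested in that comparison, with a threshold of 0.05. Comparisons were IL4 against untreated in each genotype at 10 and 24 h, labelled knockout against wild type at each time and averaged over times, the difference of the IL4 responses (interaction), and labelled knockout against wild type in TAM. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

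Gene lists were tested with limma's camera, which compares the members with all other tested genes, at a preset correlation between members of 0.01 and again with the correlation estimated from the data. Lists needed 5 tested members. They covered alternative activation, inflammatory genes, interferon response, immunosuppressive macrophage genes, MHC class I and II presentation, the cell cycle, cholesterol synthesis, fatty acid oxidation, glycolysis and hypoxia, lysosome, complement and macrophage identity, monocytes, immediate early and stress genes, and DNA methylation. Marker lists covered cell types the cultures or the sort could hold: melanoma, T and NK, B, dendritic, neutrophil, fibroblast, endothelial, erythroid and keratinocyte cells, and eosinophils, basophils and mast cells. List p-values were adjusted by Benjamini and Hochberg's method over the lists tested in a comparison, 16 in BMDM and 18 in TAM. Lists of IL4-moved genes were adjusted apart from these, over the induced and the repressed list only. Of the calls of all these lists, only that of genes repressed by IL4 in TAM held with an estimated correlation. Its adjustment was thus milder than that of the other TAM lists, with which it was not adjusted jointly. Lists of genes moved at least 2-fold by IL4 came from wild-type BMDM of this series.

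The genes named in each comparison followed a rule. They were the 10 highest and 10 lowest fold changes among genes past the threshold whose groups did not overlap, or the 5 with the smallest p in a direction with fewer than 5 calls. Up to 4 members of each list with the smallest p, and Tet1, Tet2 and Tet3, were added. For the average over times and the interactions no rule on overlap applied. Gene models known only by a number and small RNA genes were counted and not named. From these the text gives a part. S100a8, Cxcl9, Rn45s, Rpph1, Il4ra, Snora34, Mir350, Snord83b and Gm12238 fell outside the rule and were named after their values were seen, as were the sex-linked genes.

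The groups, comparisons, gene lists, naming rule and most alternatives were chosen before the data were examined. The alternatives were a pseudocount of 0.1, no filter or a stricter filter, median-of-ratios and quantile scaling, no intensity trend, summed repeated symbols, array weights, only the libraries of the groups compared, and leaving out each library in turn. Chosen after seeing the data were the sets of TAM libraries 1 to 4 and 5 to 8, as a block or separately, with and without wild-type library 8, the averaging of labelled knockout libraries 3 and 4, which agreed more closely than other TAM pairs, the estimated correlation together with another setting, and leaving out short RNA genes, unnamed models and ribosomal pseudogenes. Without 1 of 2 libraries of a group, the remaining one was assumed to vary like the other groups.

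The procedure was tested on simulated data in which 100 genes were changed 2-fold and another 100 genes 4-fold. The 2-fold change was recovered for 96% to 100% of its genes in the BMDM comparisons of groups and for 59% in TAM. The 4-fold change was recovered for 100% and 94%, and there were 7 to 13 false calls. Changed genes were drawn from those above a low level. The noise was normal, independent between genes and libraries, and alike in every group. No outlying library or set of libraries was simulated, so these shares describe simpler data than the deposited ones.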

Results

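The series measured gene expression in mouse macrophages labelled as wild type or as knockout of Tet2, an enzyme that oxidises 5-methylcytosine in DNA. RNA was sequenced from 12 libraries of bone marrow-derived macrophages (BMDM), grown for 7 days from marrow labelled wild type or Tet2 knockout and then left untreated or exposed for 10 or 24 h to interleukin 4 (IL4), added at 20 ng/ml. IL4 is a type 2 cytokine that drives macrophages toward alternative activation. Each of the 6 genotype and time groups had 2 libraries, which the design text calls biological replicates. A further 8 libraries came from tumour-associated macrophages (TAM), sorted as CD11b+F4/80+ cells from subcutaneous YUMM1.7 melanomas after 4 weeks, with 4 wild-type animals and 4 labelled as lacking Tet2 in LysM-Cre expressing myeloid cells. The series also lists 4 immunoprecipitation libraries for 5-hydroxymethylcytosine, which were not analysed here. Values were deposited as FPKM for 23309 gene models, so the total number of reads per library is unknown. Steps between low values gave relative depths of 0.86 to 1.35 in BMDM and 0.22 to 1.0 in TAM, where labelled knockout library 5 was the shallowest. Between 9708 and 9931 genes reached 1 FPKM in a BMDM library, and between 9638 and 10611 in a TAM library. The BMDM libraries were depleted of ribosomal RNA, and the RNA component of ribonuclease P (Rpph1) took 11.1% to 16.5% of their total FPKM. All fold changes below are differences of log2(FPKM + 1), given with the standard error (SE), and they understate the change of genes expressed at a low level.

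Tet2, the targeted gene, did not pass between genotypes at any BMDM time or in TAM. In untreated BMDM the 2 wild-type libraries had 4.11 and 5.91 FPKM of Tet2, and the 2 labelled knockout had 4.02 and 4.48. At 10 h these were 8.74 and 8.81 against 7.22 and 8.19, and at 24 h 9.38 and 9.82 against 11.3 and 10.3. The log2 difference of Tet2 was −0.18 ± 0.13 at 0 h (limma, adjusted p = 0.576), −0.17 ± 0.13 at 10 h (0.837) and 0.16 ± 0.13 at 24 h (0.506). At 10 h both labelled knockout libraries lay below both wild-type ones, and at 24 h both lay above. Without replicate 1 of untreated wild type, Tet2 passed as lower at 0 h (−0.40, adjusted p = 0.0436), and so did Tet3 (−0.69, 0.0180). In TAM the 4 wild-type libraries had 7.75 to 16.1 FPKM of Tet2 and the 4 labelled knockout had 14.4 to 19.0, a log2 difference of 0.36 ± 0.22 (adjusted p = 0.418). IL4 itself raised Tet2 in wild-type BMDM by 0.84 ± 0.13 at 24 h (adjusted p = 5.1e-04). With all libraries Tet3 did not pass between genotypes either, with log2 differences of −0.31 ± 0.20 to 0.14 ± 0.20 in BMDM (adjusted p = 0.518 to 1.00) and −0.08 ± 0.13 in TAM (0.759), and Tet1 stayed below 0.1 FPKM in every library. The labels do not say which part of Tet2 was removed, and a value for the whole gene model can miss the loss of single exons. The value does not separate the genotypes in one direction, so the groups are called labelled knockout in the following.

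The first question was how wild-type macrophages responded to IL4. After 24 h, Arg1, which encodes the enzyme that splits arginine, rose from 1.20 ± 0.245 to 1028 ± 52.5 FPKM (mean ± SD, n = 2 libraries per group). That is a log2 change of 8.87 ± 0.12 (SE; limma, adjusted p = 2.4e-11). Retnla, a secreted marker of alternative activation, rose by 9.13 ± 0.18, the C-type lectin gene Mgl2 by 6.60 ± 0.17, the chitinase-like gene Chi3l3 by 5.94 ± 0.14 and the chemokine gene Ccl24 by 5.94 ± 0.15 (n = 2 per group; adjusted p at most 8.2e-10). The iron exporter gene Slc40a1 changed by −4.32 ± 0.10 and the receptor gene Gpr34 by −3.93 ± 0.18. At 10 h the response was already large, with Retnla at 6.84 ± 0.18, Arg1 at 6.30 ± 0.12 and Socs1, a feedback inhibitor of cytokine signalling, at 5.17 ± 0.22. In all, 4461 of 10510 tested genes passed at 10 h (2965 rose, 1496 fell) and 5255 at 24 h (3120 rose, 2135 fell). The groups did not overlap for 72.2% of the tested genes at 10 h and 66.1% at 24 h, where 33% would do so by chance with 2 against 2 libraries.

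**Figure D1:**
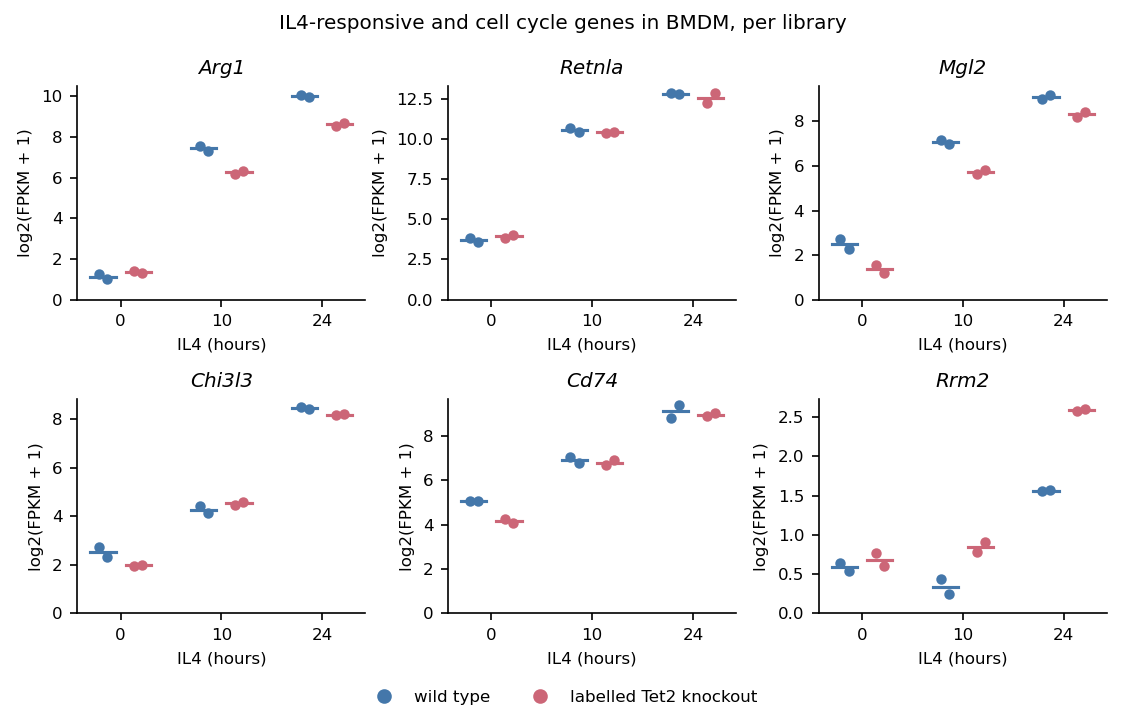
Expression of 6 genes in each BMDM library as log2(FPKM + 1) against hours of IL4; points are libraries, bars are means of 2 libraries, blue is wild type and red is labelled knockout. Arg1 at 24 h lay at 991 and 1065 FPKM in wild type and at 373 and 417 FPKM in the labelled knockout.

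The alternative activation list rose almost as a whole in wild-type BMDM. Of its 30 measured members, 26 rose, 0 fell and 4 did not pass at 10 h (26 and 0 adjusted over the list alone), with a median log2 change of 2.06 (limma's camera, adjusted p = 6.4e-18; adjusted p = 0.168 with an estimated correlation). At 24 h, 29 rose, 1 fell and 0 did not pass (29 and 1 adjusted over the list alone), with a median of 3.32 (adjusted p = 1.4e-20; adjusted p = 0.123 with an estimated correlation). The member that fell was Il4ra, which encodes the IL4 receptor and was named after its value was seen. All 9 measured genes of antigen presentation on MHC class II rose at 24 h (9 adjusted over the list alone; median 2.26, adjusted p = 1.4e-06; adjusted p = 0.252 with an estimated correlation), among them the invariant chain gene Cd74 (4.04 ± 0.17) and the class II transactivator gene Ciita (2.78 ± 0.13). Of 19 cholesterol synthesis genes, 14 rose and 1 fell at 10 h (adjusted p = 7.5e-04; 0.733 with an estimated correlation). At 24 h 17 rose and 1 fell (median 1.31, adjusted p = 6.1e-08; adjusted p = 0.252 with an estimated correlation), led by Fdps (2.71 ± 0.14) and Idi1 (2.31 ± 0.12), both enzymes of isoprenoid synthesis. For both times the counts were identical when adjusted over the list alone. Of 25 cell cycle genes, 21 rose at 24 h (22 adjusted over the list alone), including the topoisomerase gene Top2a (1.46 ± 0.13) and the kinesin gene Kif11 (1.17 ± 0.10; median 0.72, adjusted p = 5.3e-06; adjusted p = 0.252 with an estimated correlation).

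Other lists moved less uniformly. At 24 h 17 of 21 glycolysis and hypoxia genes rose and 2 fell (adjusted p = 2.8e-04), with Pgk1 at 1.98 ± 0.13 and Ndrg1 at −1.75 ± 0.12. MHC class I genes rose in 10 of 13 cases (adjusted p = 0.00204), fatty acid oxidation genes in 12 of 17 with 1 falling (0.00750), and immediate early and stress genes in 12 of 16 with 1 falling (0.00325); each of these 4 lists had an adjusted p = 0.463 with an estimated correlation. Adjusted over the list alone, the counts were 17 and 2, 10 and 0, 12 and 1, and 13 and 2. Interferon response genes went the other way: 13 of 33 fell and 5 rose (14 and 5 adjusted over the list alone; median −0.37, adjusted p = 0.0237; adjusted p = 0.770 with an estimated correlation). Ifit3, an interferon-induced gene, changed by −2.22 ± 0.33 and the chemokine gene Cxcl10 by −1.51 ± 0.18, whereas the guanylate-binding protein gene Gbp2 rose by 1.91 ± 0.13. At 10 h the interferon list had 10 falling and 5 rising (median −0.41, adjusted p = 0.0177), the MHC class I list 8 of 13 rising (0.0177) and the complement and macrophage identity list 8 of 17 falling with 2 rising (0.0203), each with an adjusted p = 0.733 with an estimated correlation. With median-of-ratios scaling the interferon list did not pass at 10 h (adjusted p = 0.0613) or at 24 h (0.0591). The inflammatory, immunosuppressive, lysosome, monocyte and DNA methylation lists did not pass at either time. Single members did change within them: the chemokine gene Ccl7 rose by 4.15 ± 0.16 at 24 h, the fibronectin gene Fn1 by 4.32 ± 0.13 and S100a4 by 3.51 ± 0.15. Dividing the libraries by median-of-ratios factors lowered the median change of all genes at 10 h by 0.13, and quantile normalization by 0.11. Rises were 66.5% of the calls at 10 h as deposited, 48.7% with median-of-ratios scaling (2357 rose, 2478 fell) and 48.9% with quantile normalization, and at 24 h 59.4%, 50.2% and 47.6% (2577 rose, 2836 fell). Without replicate 1 of the 10 h wild-type group 2859 genes passed at 10 h, and with only the libraries compared 2908 passed at 24 h.

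The macrophages labelled knockout also responded to IL4. Retnla rose by 8.62 ± 0.18 at 24 h, Mgl2 by 6.93 ± 0.17, Chi3l3 by 6.22 ± 0.14 and Arg1 by 7.28 ± 0.12 (n = 2 per group; limma, adjusted p at most 5.6e-10). Arg1 reached 395 ± 31.4 FPKM (mean ± SD, n = 2) from 1.54 ± 0.123 FPKM. At 10 h 4074 genes passed (2540 rose, 1534 fell) and at 24 h 4590 (2789 rose, 1801 fell); without replicate 2 of the untreated labelled knockout the count at 10 h was 2708. Both counts lay below those of wild type. With only the libraries compared this order turned. The labelled knockout then had 5532 genes and wild type 3362 at 10 h, and 5714 and 2908 at 24 h. The groups did not overlap for 77.7% and 79.4% of the tested genes, against 33% by chance. Rises were 62.3% of the calls at 10 h, 49.9% with median-of-ratios scaling and 48.8% with quantile normalization, and at 24 h 60.8%, 50.8% and 48.3%. The alternative activation list had 26 of 30 rising at 10 h (28 adjusted over the list alone; adjusted p = 3.2e-19; adjusted p = 0.144 with an estimated correlation). At 24 h 28 rose and 1 fell (28 and 1 adjusted over the list alone; median 3.09, adjusted p = 1.6e-20; adjusted p = 0.0916 with an estimated correlation). At 24 h 24 of 25 cell cycle genes rose (24 adjusted over the list alone; median 1.09, adjusted p = 8.2e-11; adjusted p = 0.0916 with an estimated correlation), with the ribonucleotide reductase gene Rrm2 at 1.91 ± 0.10 and Top2a at 2.04 ± 0.13. All 9 MHC class II genes rose (adjusted p = 3.7e-07; adjusted p = 0.276 with an estimated correlation), as did 15 of 19 cholesterol synthesis genes (17 adjusted over the list alone; 1 fell; adjusted p = 1.3e-06; adjusted p = 0.363 with an estimated correlation). Of 33 interferon response genes 19 fell and 2 rose (19 and 3 adjusted over the list alone; adjusted p = 4.2e-04; adjusted p = 0.490 with an estimated correlation).

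Across genes, the IL4 response of the labelled knockout followed that of the wild type, with Pearson's r = 0.84 and Spearman's rho = 0.88 at 10 h and 0.83 and 0.80 at 24 h over 10510 genes, which are not independent replicates. At 24 h 2174 genes rose in both and 1311 fell in both, where independent lists would share 828 and 366. Each genotype had its own untreated libraries, so no library was shared.

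**Figure D2:**
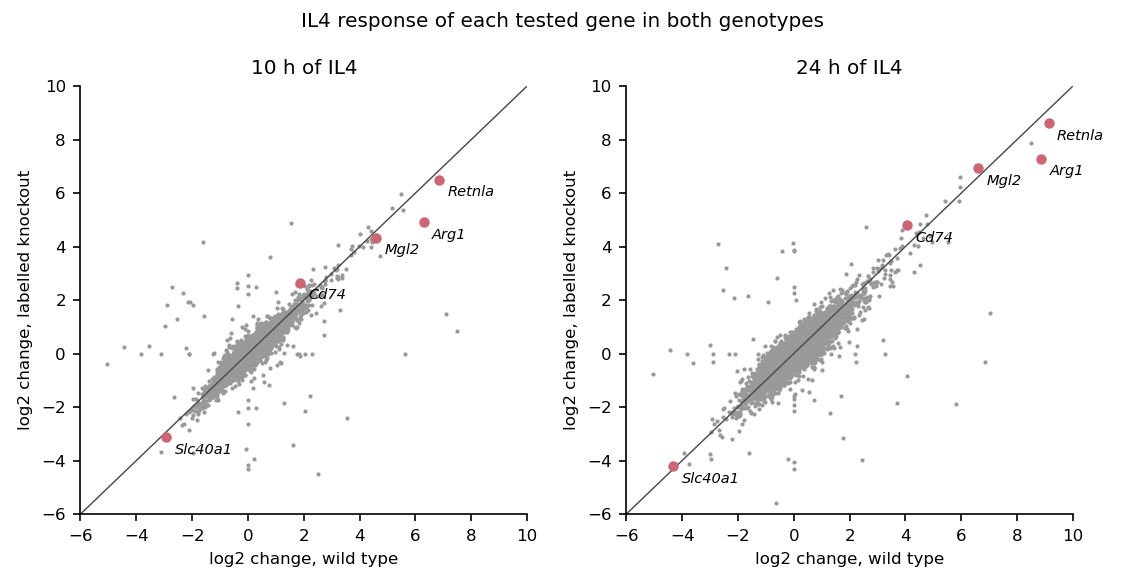
Log2 change after IL4 in the labelled knockout (y axis) against wild type (x axis) for 10510 tested genes at 10 h and 24 h; each grey point is a gene, the line marks equal change and 5 named genes are in red. Arg1 lay below the line at both times, at 6.30 in wild type and 4.91 in the labelled knockout at 10 h and at 8.87 and 7.28 at 24 h.

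The next comparison asked how the genotypes differed at each time. In untreated BMDM, Cd5l, which encodes a secreted macrophage scavenger protein, was 592 ± 22.9 FPKM in the labelled knockout and 84.5 ± 23.6 in wild type (mean ± SD, n = 2), a log2 difference of 2.82 ± 0.17 (limma, adjusted p = 1.3e-05). Also higher were the collagen gene Col1a2 by 1.87 ± 0.10, the matrix protein gene Sparc by 1.87 ± 0.10, the matrix Gla protein gene Mgp by 2.04 ± 0.20, the collagen chaperone gene Serpinh1 by 1.52 ± 0.16 and the metalloproteinase inhibitor gene Timp1 by 2.13 ± 0.13 (n = 2 per group; adjusted p at most 6.4e-04). Col1a2, Dcn and Postn, the 3 genes of the fibroblast marker list that reached the level for testing, were all higher, by 1.87, 1.54 and 1.34. The receptor tyrosine kinase gene Axl was higher by 1.10 ± 0.13. The lower genes included the adhesion molecule gene Cadm1 (−2.09 ± 0.11), the lysosomal thiol reductase gene Ifi30 (−1.23 ± 0.10), the transporter gene Abca9 (−1.32 ± 0.09) and the purinergic receptor gene P2ry12 (−1.27 ± 0.11). Of 19 cholesterol synthesis genes 5 were higher and 0 lower (11 and 0 adjusted over the list alone; median 0.32, camera adjusted p = 2.9e-06; adjusted p = 0.937 with an estimated correlation). Of 9 MHC class II genes 2 were lower (4 lower and 1 higher adjusted over the list alone; median −0.22, adjusted p = 8.4e-04; adjusted p = 0.937 with an estimated correlation). The complement and macrophage identity list passed as lower (adjusted p = 0.0487; 0.937 with an estimated correlation) although its median was 0.01, and 1 of 17 members was higher and 1 lower (1 and 5 adjusted over the list alone). In total 199 genes were higher and 85 lower, 70.1% against 63.7% with median-of-ratios scaling and 60.1% with quantile normalization (217 higher, 144 lower). Groups did not overlap for 42.5% of the tested genes, against 33% by chance. The count depended on single libraries: 1392 genes passed without replicate 1 of wild type, 136 without replicate 2, and 98 and 122 without replicates 1 and 2 of the labelled knockout. It was 118 with only the libraries compared, 138 with 1 FPKM required in every library and 459 with no filter.

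**Figure D3:**
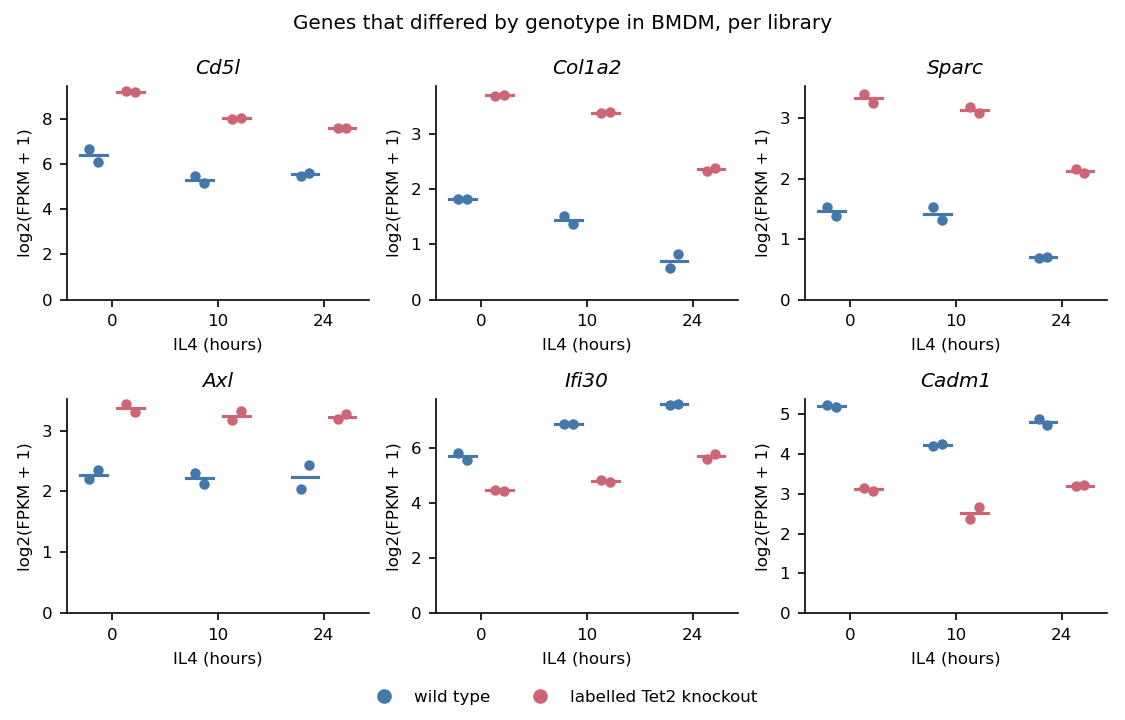
Expression of 6 genes in each BMDM library as log2(FPKM + 1) against hours of IL4; points are libraries, bars are means of 2 libraries, blue is wild type and red is labelled knockout. Cd5l was 190.0 to 608 FPKM in the 6 labelled knockout libraries and 34.3 to 101 FPKM in the 6 wild-type libraries.

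After 10 h of IL4 the same comparison gave 184 higher and 115 lower genes. Cd5l was again higher in the labelled knockout, by 2.71 ± 0.17, as were Col1a2 (1.94 ± 0.10), the collagen cross-linking enzyme gene Lox (1.92 ± 0.12), Serpinh1 (1.79 ± 0.16), Sparc (1.71 ± 0.10) and Axl (1.03 ± 0.13; n = 2 per group; limma, adjusted p at most 0.00200). Arg1 was lower by −1.18 ± 0.12 (adjusted p = 5.3e-04), at 75.7 ± 5.58 FPKM against 173 ± 19.2 FPKM in wild type (mean ± SD, n = 2). Mgl2 differed by −1.36 ± 0.17, Ifi30 by −2.06 ± 0.10, Cadm1 by −1.71 ± 0.11 and F13a1, a monocyte gene for a clotting factor subunit, by −1.21 ± 0.12. Nos2, which encodes the nitric oxide synthase that competes with arginase for arginine, was higher by 0.70 ± 0.10 (adjusted p = 0.00302). None of the 33 interferon response genes passed alone (limma; 0 adjusted over the list alone, 8 at an unadjusted p under 0.05), but 30 were higher, with a median of 0.35 (adjusted p = 1.8e-04; adjusted p = 0.804 with an estimated correlation). The MHC class I list (0 of 13 past limma's threshold, 1 at an unadjusted p under 0.05; median 0.17, adjusted p = 0.0158) and the cell cycle list (1 higher and 1 lower of 25; median 0.16, 0.00246) passed as higher and the complement and macrophage identity list as lower (6 lower and 1 higher of 17; median −0.13, 1.8e-04), all 3 with an adjusted p = 0.804 with an estimated correlation. Higher genes were 61.5% of the calls, 56.8% with median-of-ratios scaling and 51.8% with quantile normalization (191 higher, 178 lower). Groups did not overlap for 51.6% of the tested genes, against 33% by chance. Leaving out replicate 1 or 2 of wild type left 126 and 94 genes, and leaving out replicate 1 or 2 of the labelled knockout left 126 and 122. Requiring 1 FPKM in every library left 149 (70 higher, 79 lower), which turned the balance.

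After 24 h of IL4 genes of the cell cycle were higher in the labelled knockout. Of 25 measured members 15 were higher and 0 lower (22 and 0 adjusted over the list alone), all 25 lay above wild type, and the median was 0.54 (camera, adjusted p = 6.2e-13; adjusted p = 0.114 with an estimated correlation). Rrm2 was higher by 1.03 ± 0.10, Top2a by 0.99 ± 0.13, the cyclin-dependent kinase gene Cdk1 by 0.74 ± 0.10 and the replication helicase gene Mcm4 by 0.71 ± 0.09, and Uhrf1, which brings the maintenance DNA methyltransferase to replicated DNA, by 1.05 ± 0.09 (n = 2 per group; limma, adjusted p at most 0.00303). Arg1 was lower by −1.38 ± 0.12 (adjusted p = 2.8e-04), the coagulation factor gene F10 by −1.34 ± 0.10, the ribonuclease gene Ear3 by −2.33 ± 0.16, the angiogenic factor gene Vegfa by −0.84 ± 0.09 and the folate receptor gene Folr2 by −1.22 ± 0.15. Cd5l (2.05 ± 0.17), Col1a2 (1.66 ± 0.10), Sparc (1.43 ± 0.10), Dcn (0.97 ± 0.15) and Axl (0.99 ± 0.13) stayed higher, and Ifi30 (−1.90 ± 0.10) and Cadm1 (−1.60 ± 0.11) lower. The complement and macrophage identity list had 6 of 17 lower and 1, Axl, higher (median −0.31, adjusted p = 0.00119; adjusted p = 0.511 with an estimated correlation). Also lower as lists were the inflammatory genes (3 of 24 lower; adjusted p = 0.00119), the immediate early genes (1 of 16; 0.00167), glycolysis and hypoxia (2 of 21 lower, 1 higher; 0.00686), interferon response (0 of 33; 0.0387), MHC class II (1 of 9; 0.0387) and lysosome (0 of 22; 0.0439). Adjusted over the list alone, 3, 4, 3, 0, 1 and 0 were lower, with 1 higher in the immediate early and glycolysis lists, and 3 interferon and 4 lysosome genes had an unadjusted p under 0.05 (limma). With an estimated correlation none of these 6 lists passed (adjusted p = 0.478 to 0.722). The interferon call was lost with median-of-ratios scaling (adjusted p = 0.107) and the MHC class II and lysosome calls with a pseudocount of 0.1 (0.0537 and 0.0505). The neutrophil marker list was lower too, with 2 of 9 lower (4 adjusted over the list alone; adjusted p = 0.00271; adjusted p = 0.478 with an estimated correlation). In total 556 genes were higher and 225 lower, 71.2% against 48.2% with median-of-ratios scaling (582 higher, 626 lower) and 53.0% with quantile normalization. With only the 4 libraries compared, 18 genes passed (6 higher, 12 lower), and Arg1, F10, Vegfa, Folr2, Rrm2, Top2a, Cdk1, Mcm4, Uhrf1, Axl and Dcn were not among them (adjusted p = 0.0575 to 0.112). Groups did not overlap for 50.5% of the tested genes, against 33% by chance. Without replicate 1 of wild type 1257 genes passed (514 higher, 743 lower), and without replicates 1 and 2 of the labelled knockout 178 and 156 (73 higher, 83 lower without replicate 2). The balance thus turned to lower genes in 4 settings.

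Averaged over the 3 times, 742 genes were higher and 303 lower in the labelled knockout, led by Cd5l (2.53 ± 0.10; limma, adjusted p = 1.9e-07), Col1a2 (1.82 ± 0.06), Sparc (1.67 ± 0.06) and Mgp (1.60 ± 0.11) on the higher side. On the lower side stood Cadm1 (−1.80 ± 0.06), Ifi30 (−1.73 ± 0.06), Abca9 (−1.37 ± 0.05) and Mgl2 (−1.08 ± 0.10). For these averages n = 6 libraries per genotype, 2 at each of the 3 times, which the fit treats as independent. Whether cultures of different times came from the same animals is not known here. The alternative activation list split: 4 of 30 were higher and 6 lower (4 and 6 adjusted over the list alone; median 0.04, camera adjusted p = 0.399), with Arg1 at −0.78 ± 0.07, the lectin gene Clec10a at −0.42 ± 0.07 and the collagenase gene Mmp13 at 0.71 ± 0.09. Of the cell cycle genes 17 of 25 were higher (20 higher and 1 lower adjusted over the list alone; adjusted p = 5.1e-09; adjusted p = 0.256 with an estimated correlation). Of the complement and macrophage identity genes 6 were lower, among them the complement gene C1qa (−0.79 ± 0.11) and Folr2 (−0.94 ± 0.08), and Axl was higher (1.04 ± 0.08; list adjusted p = 1.5e-05; adjusted p = 0.607 with an estimated correlation). Of 9 MHC class II genes 4 were lower (5 adjusted over the list alone), with H2-Ab1 at −0.73 ± 0.12 and H2-Aa at −0.58 ± 0.11 (list adjusted p = 0.00137; adjusted p = 0.607 with an estimated correlation). The cholesterol list was higher (3 of 19; adjusted p = 0.0152) and the immediate early list lower (2 of 16; 0.0270), both with an adjusted p = 0.705 with an estimated correlation, and the neutrophil list lower (1 of 9, 2 adjusted over the list alone; 0.0133, or adjusted p = 0.607 with an estimated correlation). Cd79b, the only measured B cell marker, was higher by 0.76 ± 0.12. Fold changes between genotypes correlated across genes with r = 0.35 between 0 and 10 h, 0.32 between 10 and 24 h and 0.11 between 0 and 24 h (Spearman's rho 0.44, 0.20 and 0.06); 108 genes were higher and 54 lower at both 0 and 10 h, where independent lists would share 3.48 and 0.930. Higher genes were 71% of the calls, 56.5% with median-of-ratios scaling (700 higher, 539 lower) and 54.2% with quantile normalization. Without replicate 1 of untreated wild type 1789 genes passed. The count was 639 and 668 without replicates 1 and 2 of the untreated labelled knockout, 667 and 613 without replicates 1 and 2 of wild type at 10 h, 637 without replicate 2 of the labelled knockout at 10 h and 656 without its replicate 2 at 24 h, and 645 with 1 FPKM required in every library.

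Whether the IL4 response itself differed between genotypes was tested as an interaction, the log2 change in the labelled knockout minus that in wild type. Larger and smaller give the sign of this value only. For genes that IL4 lowered, a negative value is a stronger fall and a positive one a weaker fall. At 24 h 10 genes had a larger and 21 a smaller response in the labelled knockout. Arg1 had a smaller one by −1.59 ± 0.17 on the log2 scale (n = 2 per group; limma, adjusted p = 0.00340), as had Timp1 (−1.69 ± 0.18), F10 (−1.36 ± 0.15) and Ear3 (−2.21 ± 0.22), and the endothelin receptor gene Ednrb had a larger one (1.38 ± 0.15). The calls of these 5 genes held without each single library, and that of Ear3 was lost with a pseudocount of 0.1 (−4.66, adjusted p = 0.113). At 10 h the difference in the Arg1 response was −1.39 ± 0.17 (adjusted p = 0.0113). That call held only without replicate 1 of untreated wild type or replicate 2 of wild type at 10 h. Without each of the other 6 libraries its adjusted p was 0.0529 to 0.0940, at a log2 difference of −1.46 to −1.27. At 10 h 6 genes had a larger and 4 a smaller response. The 4 were Arg1 and, named here after their values were seen, the small RNA genes Mir350 and Snord83b and the unnamed gene model Gm12238, a class in which reads are hard to assign. Over all genes, median-of-ratios scaling gave 46 larger and 111 smaller responses at 24 h and quantile normalization 42 and 73. The total at 24 h was 17 with a pseudocount of 0.1, 14 with only the libraries compared, 96 with no filter and 8 with 1 FPKM required in every library, and at 10 h the 2 filters gave 31 and 2. As lists, cell cycle genes had a larger response at 24 h (1 of 25 alone, 8 adjusted over the list alone; median 0.38, camera adjusted p = 4.8e-08; adjusted p = 0.324 with an estimated correlation). The lists of inflammatory (median −0.33, adjusted p = 4.5e-05; 0.513), cholesterol synthesis (−0.35, 4.5e-05; 0.513), glycolysis and hypoxia (−0.35, 0.00159; 0.585), immediate early (−0.35, 0.00413; 0.545) and interferon genes (−0.23, 0.0171; 0.755) passed as smaller, where the value after each semicolon is the adjusted p with an estimated correlation. The interferon list fell with IL4 at 24 h in both genotypes, so its negative value is a stronger fall in the labelled knockout. No member of these 5 lists passed alone (limma): 2, 2, 2, 5 and 0 were smaller adjusted over the list alone, and 6, 9, 11, 6 and 2 had an unadjusted p under 0.05. At 10 h the cholesterol (median −0.29, adjusted p = 9.2e-06) and immediate early lists (−0.09, 0.0392) were smaller and the interferon (0.08, 0.0227) and MHC class II lists (0.09, 0.0419) larger, with no member past limma's threshold (8, 3, 3 and 1 at an unadjusted p under 0.05). None of the 4 lists passed with an estimated correlation (adjusted p = 0.770 to 0.930). The number of passing genes without single libraries was 5 to 62 at 10 h and 11 to 1169 at 24 h. At 10 h it was 62 without replicate 1 of untreated wild type, 5 without replicate 2, 6 without replicate 1 of wild type at 10 h and 7 (3 larger, 4 smaller) without replicate 2 of the labelled knockout at 10 h. At 24 h it was 1169 without replicate 1 of untreated wild type, 16 without replicate 2, 14 and 17 without replicates 1 and 2 of the untreated labelled knockout, 149 without replicate 1 of wild type at 24 h, 38 (20 larger, 18 smaller) without its replicate 2, and 11 and 12 without replicates 1 and 2 of the labelled knockout at 24 h.

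The genes that IL4 moved at least 2-fold in wild type were also followed as lists between genotypes, each taken from one time and tested at the other so that list and test shared no treated library. The 548 genes induced at 10 h (42 higher, 19 lower) had a median log2 difference of 0.05 between genotypes at 24 h (camera, adjusted p = 0.899), and the 209 repressed at 10 h (15 higher, 13 lower) one of −0.01 (0.0946). At 10 h the 701 genes induced at 24 h (31 higher, 15 lower) had a median of 0.07 (adjusted p = 0.0739) and the 356 repressed (17 higher, 17 lower) one of −0.01 (0.117). None of the 4 lists passed.

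**Figure D4:**
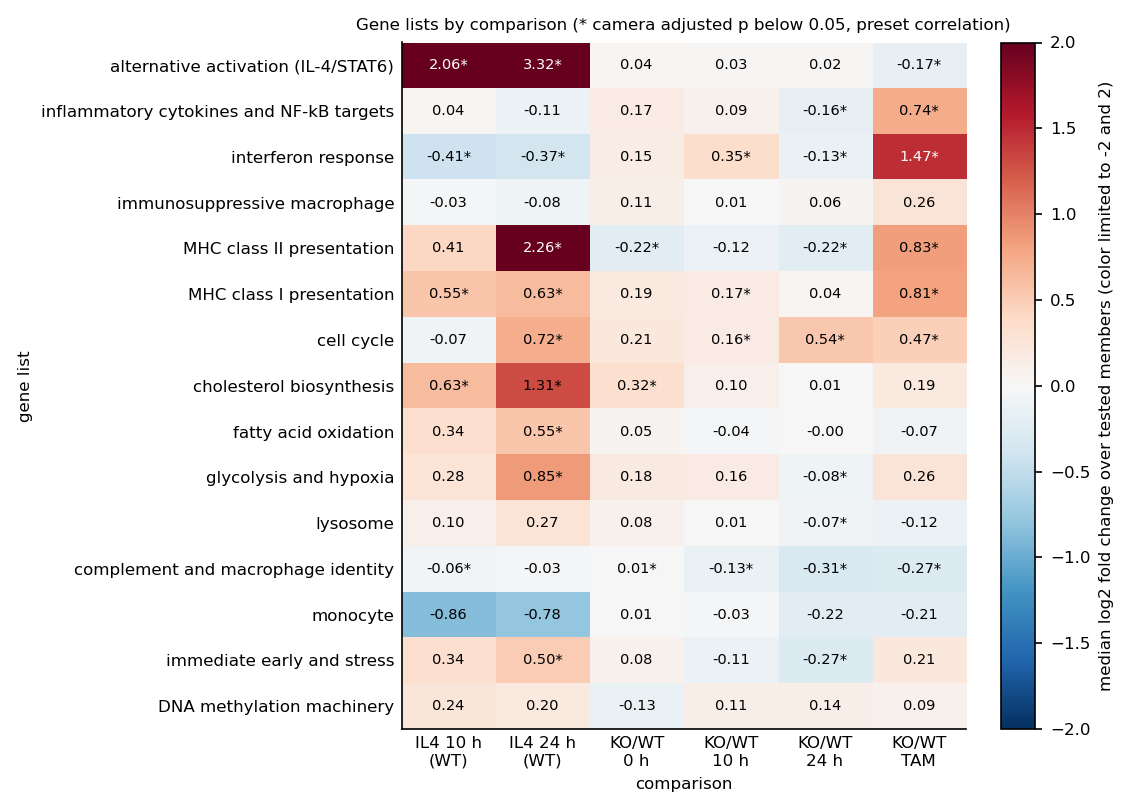
Median log2 fold change over the tested members of 15 gene lists (vertical axis) in 6 comparisons (horizontal axis), with the value in each cell and color limited to −2 and 2; an asterisk marks a camera adjusted p under 0.05 with the preset correlation. The alternative activation list rose with IL4 (medians 2.06 and 3.32) and stayed near 0 between genotypes in BMDM, and no asterisk holds with an estimated correlation.

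In macrophages sorted from tumours, animals labelled as lacking Tet2 in myeloid cells were compared with wild type. Of 9897 tested genes 10 passed, 5 higher and 5 lower in the labelled knockout, against 1 higher and 5 lower with median-of-ratios scaling and with quantile normalization alike. Groups did not overlap for 1228 of the tested genes (12.4%), so a separation of the groups was not particular to the genes named here. With array weights 2055 genes passed (1509 higher, 546 lower). The weights were 4.38 and 3.05 for labelled knockout libraries 3 and 4 and 3.10 for wild-type library 1. All others had weights of 0.24 (wild-type library 8) to 0.86 (wild-type library 2). Calls with array weights thus rest mostly on the former libraries, among them the pair whose independence is left open below. Clec10a, a lectin gene of alternatively activated macrophages, was 4.50 ± 1.17 FPKM in the labelled knockout and 19.0 ± 3.21 in wild type (mean ± SD, n = 4 each), a log2 difference of −1.87 ± 0.18 (limma, adjusted p = 0.0150). The sulfotransferase gene Sult1a1 was lower by −2.42 ± 0.28 (adjusted p = 0.0358), the interleukin 36 receptor gene Il1rl2 by −1.22 ± 0.16 (0.0471) and the mTOR inhibitor gene Deptor by −0.87 ± 0.10 (0.0358). The fifth was Snora34, a small nucleolar RNA outside the naming rule that was named after its value was seen. It was listed at 0 in the 4 labelled knockout libraries and at a mean of 292 ± 281 FPKM in wild type. Cd276, which encodes the immune checkpoint protein B7-H3, was higher, at 13.8 ± 1.31 against 5.23 ± 0.704 FPKM (1.25 ± 0.12, adjusted p = 0.0150), and so were Parp11 (1.13 ± 0.15), Bin2 (0.96 ± 0.12), Tssc1 (0.84 ± 0.10) and Abi3 (0.81 ± 0.10). Arg1 did not pass: it was 1.37 to 6.55 FPKM in the labelled knockout and 25.6 to 88.3 in wild type without overlap, a log2 difference of −3.21 ± 0.45 (n = 4 per group; adjusted p = 0.0538). It passed with libraries 1 to 4 and 5 to 8 as a block (adjusted p = 0.0288; −2.92, 0.0261 with wild-type library 8 left out as well), without wild-type library 8 alone (−2.84, 0.0355), with array weights (0.00231) and with 1 FPKM required in every library (0.0409). Arg1 did not pass with median-of-ratios scaling (−3.31, limma, adjusted p = 0.0577) or quantile normalization (−3.37, 0.0801). Nor did it pass within libraries 1 to 4 (0.200) or within 5 to 8 (0.0592). Without each library in turn the differences of the 9 named genes that passed hardly moved. They were −2.0 to −1.75 for Clec10a, 1.18 to 1.32 for Cd276, −0.92 to −0.83 for Deptor and −2.67 to −2.24 for Sult1a1. Each lost its call without at least 4 of the 8 libraries, with adjusted p up to 0.102 for Clec10a, 0.115 for Cd276 and 0.191 for the others. Parp11, Bin2, Tssc1 and Abi3 also lost theirs under both rescalings (adjusted p = 0.0577 to 0.0992). The count was 1 without labelled knockout libraries 3, 4 or 5, 3 without labelled knockout library 6 or wild-type library 1, 4 without wild-type library 2, 5 without wild-type library 7, and 23 without wild-type library 8. It was 6 with no filter (3 higher, 3 lower) and with no intensity trend (2 higher, 4 lower), and 1 with labelled knockout libraries 3 and 4 averaged. These 2 agreed more closely (Pearson's r = 0.9954, SD of the log2 difference 0.179) than the other 11 pairs of TAM libraries within a group (0.8798 to 0.9825, 0.322 to 0.852) and about as closely as BMDM pairs (SD 0.132 to 0.280). They shared no identical nonzero value. However, without counts they could not be tested against sampling noise. Whether they are 2 independent samples is not settled here.

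As lists, interferon response genes were higher in TAM labelled knockout. All 35 measured members lay above wild type and none passed alone (limma; 0 adjusted over the list alone, 24 at an unadjusted p under 0.05), with a median log2 difference of 1.47 (camera, adjusted p = 7.1e-09; adjusted p = 0.604 with an estimated correlation). Isg15, an interferon-induced modifier, was at 2.26 ± 0.63 (adjusted p = 0.158) and the deubiquitinase gene Usp18 at 1.81 ± 0.45 (0.141); both passed with array weights (adjusted p = 0.00533 and 0.00503). The MHC class I list (13 measured, median 0.81, adjusted p = 0.00146), the inflammatory list (33, all above wild type, 0.74, 0.00859), the MHC class II list (11, 0.83, 0.0148) and the cell cycle list (26, 0.47, 0.0460) were also higher, with no member past limma's threshold (4, 3, 2 and 1 at an unadjusted p under 0.05). The complement and macrophage identity list was lower (19 measured, median −0.27, adjusted p = 7.0e-04), with 0 members past limma's threshold, 6 lower adjusted over the list alone and 8 at an unadjusted p under 0.05. It included the scavenger receptor gene Cd163 (−2.60 ± 0.60, adjusted p = 0.135) and the phagocytic receptor gene Mertk (−0.83 ± 0.18, 0.110), which passed with array weights (0.00485 and 0.00341) and with libraries 1 to 4 and 5 to 8 as a block without wild-type library 8 (0.0189 and 0.0305). The alternative activation list was lower (26 measured, 1 lower; 3 higher and 5 lower adjusted over the list alone; median −0.17, adjusted p = 0.00859; adjusted p = 0.408 with an estimated correlation). The alternative activation call was lost with median-of-ratios scaling (adjusted p = 0.0908). Its median was −0.02 without wild-type library 2, −0.01 without wild-type library 7 or labelled knockout library 5, and 0.02 without labelled knockout library 6, where the test still gave lower. It was −0.31 and −0.35 without labelled knockout libraries 3 and 4 and −0.27 without wild-type library 8. With a pseudocount of 0.1 it was −0.39. The fibroblast marker list was lower as well (6 measured, 0 past limma's threshold and 0 at an unadjusted p under 0.05; median −1.16, adjusted p = 0.00859). With an estimated correlation none of the 8 lists passed (adjusted p = 0.408 for alternative activation, 0.661 for the inflammatory, MHC class II and cell cycle lists and 0.604 for the others). Wild-type library 8 stood apart in several of these genes, named partly after their values were seen: Cd163 was 47.5 FPKM there and 4.99 to 7.15 in the other 3 wild-type libraries, Cxcl9, an interferon-induced chemokine gene, was 2.09 against 96.9 to 193 in the other 7 libraries, and Col1a2 was 77.2. Without it the inflammatory list had a median of 0.39 (adjusted p = 0.271), MHC class II 0.30 (0.0961), MHC class I 0.48 (0.00470), the interferon list 0.85 (1.4e-08), the complement and macrophage identity list −0.18 (1.3e-04) and the fibroblast list −0.48 (0.00630). The inflammatory median was 1.13 without wild-type library 2. Without wild-type library 7 the inflammatory and alternative activation lists had an adjusted p = 0.0600. The cell cycle call was lost with a pseudocount of 0.1 at a higher median (0.53, adjusted p = 0.0537). It was lost at medians of 0.37, 0.33 and 0.36 without wild-type libraries 1, 2 and 7 (0.149, 0.179 and 0.128), and at 0.21 and 0.30 without labelled knockout libraries 5 and 6 (0.614 and 0.440).

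The TAM libraries also split by number, which the labels do not explain. S100a8, a calprotectin gene abundant in neutrophils, was 3433 to 10588 FPKM in libraries 1 to 4 and 488 to 764 in libraries 5 to 8, with each genotype in both sets. Libraries 5 to 8 differed from 1 to 4 in 216 genes (80 higher, 136 lower; limma). Within libraries 1 to 4, Arg1 differed between genotypes by −3.28 ± 0.58 and within 5 to 8 by −3.15 ± 0.58, Clec10a by −1.83 ± 0.21 and −1.92 ± 0.21, and Cd276 by 1.29 ± 0.18 and 1.21 ± 0.18 (n = 2 per genotype in each set). None of these genes passed within libraries 1 to 4 (limma, adjusted p = 0.200, 0.120 and 0.190). Within 5 to 8 Clec10a (0.0244) and Cd276 (0.0425) passed and Arg1 did not (0.0592). The labelled knockout side of libraries 1 to 4 was libraries 3 and 4, whose independence is not settled. The genotypes differed in 1 gene within libraries 1 to 4 and in 134 within 5 to 8 (81 higher, 53 lower), and a test of the difference between the sets called 2 genes (1 higher, 1 lower). With the sets as a block 31 genes passed (16 higher, 15 lower), and 135 without wild-type library 8 (89 higher, 46 lower). The ribosomal transcript Rn45s was 3978 to 11529 FPKM in wild-type libraries 2, 7 and 8 and 312 to 509 in the other 5. These 5 were wild-type library 1 and every labelled knockout library, so high values occurred only in wild type. The TAM comparison of genotypes therefore carries this difference between libraries, and its effect on other genes was not tested.

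**Figure D5:**
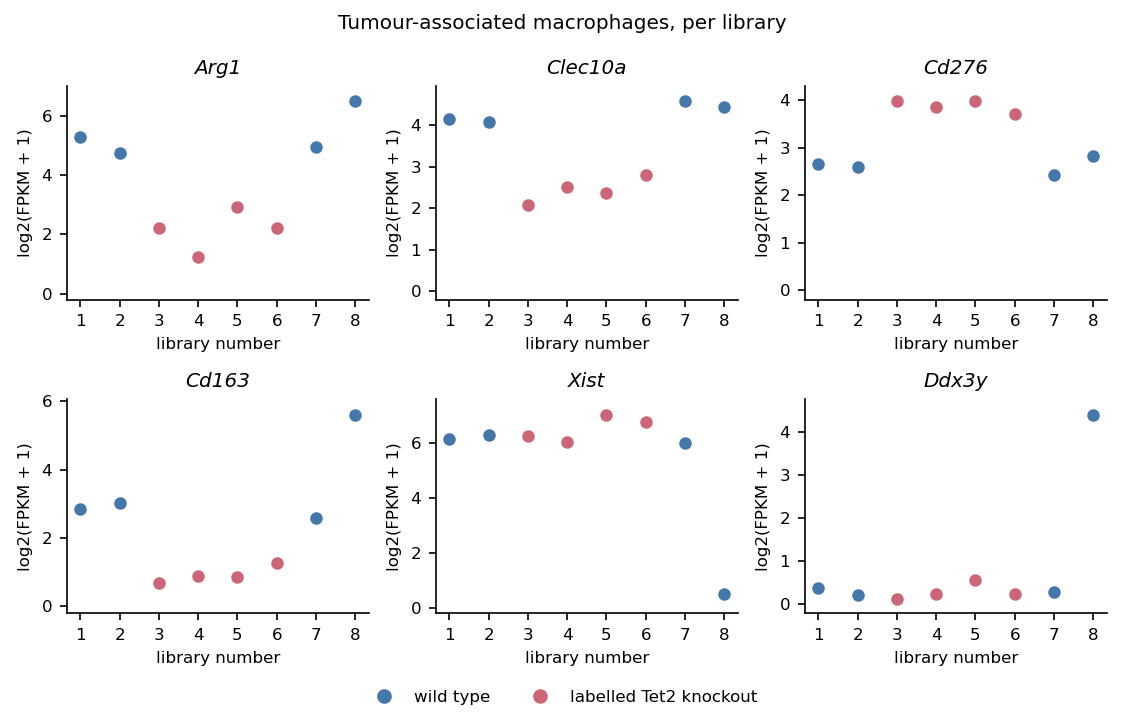
Expression of 6 genes in the 8 TAM libraries as log2(FPKM + 1) against library number; points are single libraries, blue is wild type and red is labelled knockout. Arg1 and Clec10a were lower and Cd276 higher in all 4 labelled knockout libraries, and library 8 had 0.414 FPKM of Xist against 62.4 to 128 FPKM in the other 7.

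Genes that IL4 moved at least 2-fold in wild-type BMDM at 24 h were then looked up in TAM. Of 300 repressed genes with a value, none passed alone (limma), and 54% lay below wild type in the labelled knockout against 38.1% of all tested genes, with a median log2 difference of −0.08 against 0.09 (camera, adjusted p = 5.8e-05; p = 0.00311 with an estimated correlation). The median of the repressed genes was −0.04 without wild-type library 8 (adjusted p = 4.6e-05) and −0.16 with median-of-ratios scaling (0.00156). Both held with an estimated correlation (camera, adjusted p = 0.0114 and 0.00549, over the induced and repressed lists only). The 584 induced genes, with 1 higher and 1 lower, had a median of 0.18 (adjusted p = 0.171). Without labelled knockout library 6 the induced list passed as higher (median 0.22, adjusted p = 0.0376), and with median-of-ratios scaling it did at a median of 0.06 (0.0411). In neither case did it pass with an estimated correlation (adjusted p at least 0.125). The genotype differences of TAM and BMDM barely correlated across 9261 genes, with r = 0.05, 0.07 and 0.04 against BMDM at 0, 10 and 24 h (Spearman's rho 0.11, 0.05 and 0.09).

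Markers of other cell types set limits on what the sorted and cultured cells held. In TAM the T and NK cell list (7 measured; camera, adjusted p = 0.743), the neutrophil list (10 measured, 0.155) and the monocyte list (14 measured, 0.132) did not pass between genotypes. With the sets of libraries 1 to 4 and 5 to 8 as a block, the neutrophil list passed as lower (median −0.24, adjusted p = 0.0301) and the monocyte list did not (0.102). Both lists had an adjusted p = 0.585 with an estimated correlation. The neutrophil list also passed as lower without wild-type library 8 (median −0.74, adjusted p = 0.00775), wild-type library 7 (−0.70, 0.0324) or labelled knockout libraries 3 (−0.54, 0.0285) or 4 (−0.52, 0.0382). Its median turned positive without wild-type libraries 1 (0.10, 0.404) or 2 (0.35, 0.947) or labelled knockout library 6 (0.18, 0.585), and was −0.01 without labelled knockout library 5 (0.341). The monocyte list passed as lower without wild-type library 8 (−0.40, 0.00973) or labelled knockout libraries 3 (−0.50, 0.00885) or 4 (−0.47, 0.0249). Neither list passed with an estimated correlation, with all libraries (adjusted p = 0.661 for both) or without any single one (adjusted p at least 0.566). The monocyte median turned positive without wild-type library 2 (0.12, 0.408) or labelled knockout libraries 5 (0.12, 0.449) or 6 (0.19, 0.433). Too few members were measured to test 7 further marker lists as lists, and no member passed alone (limma). The 2 endothelial markers were at 1.83 ± 0.47 (Pecam1, adjusted p = 0.145) and 0.98 ± 0.36 (Kdr, 0.234), both higher adjusted over the list alone. Of the list of eosinophils, basophils and mast cells only Prg2 was measured, at −1.81 ± 0.45 (adjusted p = 0.141). The 3 erythroid markers were at −2.05 ± 1.07 (Hbb-b1, 0.356), −1.63 ± 0.73 (Hba-a1, 0.301) and −0.71 ± 0.35 (Alas2, 0.332). Of 4 dendritic cell markers, Xcr1 was at 0.82 ± 0.23 (0.157), higher adjusted over the list alone, Fscn1 at −1.20 ± 0.55 (0.315), Batf3 at 0.03 ± 0.35 and Ccr7 at 0.15 ± 0.38. The melanoma gene Mitf was at 0.00 ± 0.14 and the B cell gene Cd79b at 0.01 ± 0.27, and no keratinocyte marker was measured. With array weights Pecam1, Kdr, Prg2 and Xcr1 passed (1.16, 0.67, −1.36 and 0.64; adjusted p = 0.0248 to 0.0347). Within libraries 5 to 8 Hbb-b1 and Hba-a1 passed as lower (−4.88 ± 0.70 and −3.66 ± 0.39, adjusted p = 0.0422 and 0.0244) but not within 1 to 4 (0.77 ± 0.70 and 0.39 ± 0.39). The difference between the sets did not pass for either (0.222 and 0.151). In BMDM the melanoma, T and NK cell, B cell, dendritic cell, fibroblast, endothelial, eosinophil, keratinocyte and erythroid lists had 3 or fewer measured members and were not tested as lists. Besides the fibroblast genes, 4 of their members passed between genotypes, all higher. The endothelial gene Pecam1 passed at 24 h (0.64 ± 0.11, adjusted p = 0.00928) and averaged (0.40 ± 0.06, 0.00269), and Egfl7 averaged (0.36 ± 0.10, 0.0433). The eosinophil gene Ccr3 passed at 24 h (0.62 ± 0.14, 0.0236) and averaged (0.29 ± 0.08, 0.0439). Cd79b passed at 0 h (1.06 ± 0.20, 0.0188) and averaged. The averaged calls of Pecam1 and Cd79b held without each of the 12 libraries in turn. Those of Egfl7 and Ccr3 were lost without 8 and 10 of them. The calls at single times were lost without 1 (Pecam1) or 3 (Ccr3, Cd79b) of 4 libraries and with only the libraries compared. The other lists that did not pass between genotypes in TAM were immunosuppressive macrophage genes (19 measured, median 0.26, adjusted p = 0.210), cholesterol synthesis (0.132), fatty acid oxidation (0.190), glycolysis and hypoxia (0.381), lysosome (0.229), immediate early (0.280) and DNA methylation genes (0.515).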

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

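The count of splits within the TAM sets and the tests on fibroblast and neutrophil markers, on the sex-linked genes, on Arg1 without wild-type library 8 and on the Arg1 response relative to other alternative activation genes were chosen only after the results were seen. In TAM 92 pairs of a group and a measure were examined for a library far from the other 3 of its group, and 20 had one. For unrelated measures chosen beforehand chance gives about 1 in 20 groups (4.6). That number is no yardstick here. Most measures were genes named from these data, some after their values were seen, and they are not independent. Wild-type library 8 accounted for 13 of the 20, among them the Y-linked genes named after their values were seen.

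Fibroblast markers were higher in BMDM labelled knockout. Of 10 fibroblast markers, 8 were higher at all 3 times, and 25 of 30 pairs of gene and time were higher without overlap, with ratios of 2.03 to 6.55 where the level reached 1 FPKM. Averaged over times, the endothelial genes Pecam1 (0.40) and Egfl7 (0.36), the eosinophil gene Ccr3 (0.29) and the B cell gene Cd79b (0.76) passed as higher too, each by less than the 3 tested fibroblast markers (1.00 to 1.82). The 9 neutrophil markers had log2 differences of −0.45 to 0.07, and the dendritic cell genes Batf3 and Zbtb46 were at −0.21 and −0.04, so these did not rise with the fibroblast markers. Which cells carried these transcripts in the cultures is not known. The values therefore cannot decide whether a lower share of macrophages raised every other cell type alike. A larger share of fibroblast-like stromal cells in these cultures may account for the pattern and stays open, as does an effect of the genotype on the macrophages' own expression, which was not tested.

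Arg1 was lower in the labelled knockout after IL4 in BMDM and, without passing in the main fit, in TAM. Scaling of the libraries is argued against as the cause: over 3 comparisons and 2 rescalings, the ratio of the Arg1 difference to its SE nearest to 0 was −6.77. In TAM, however, Arg1 did not pass under either rescaling (limma, adjusted p = 0.0577 and 0.0801). The outlying wild-type library 8 is argued against for TAM, where the log2 difference was −2.84 without it. A weaker IL4 response of all alternative activation genes is argued against in BMDM. For each member the log2 change at 24 h in the labelled knockout was divided by that in wild type. The median ratio was 1.02 over the other induced members (quartiles 0.92 and 1.07, 29 members with Arg1). For Arg1 the ratio was 0.82 (SE 0.0194), from log2 changes of 7.28 and 8.87, with 6 others at or below it. A given ratio of log2 changes stands for a larger fold difference in a strongly induced gene than in a weakly induced one. An effect of the genotype on Arg1 could account for its lower values and stays a hypothesis. Tet2 itself did not pass between the genotypes, and 2 libraries per group are few.

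Wild-type TAM library 8 had the sex-linked pattern of a male and the other 7 that of females, whereas the protocol names male mice. Xist was 0.414 FPKM in library 8 and 62.4 to 128 in the others, and Ddx3y was 20.3, Eif2s3y 21.5, Kdm5d 4.34 and Uty 3.97 FPKM against at most 0.473 in the others. Male cells mixed into a female sample are argued against, since Xist in library 8 was 0.663% of the lowest other library. All 4 Y-linked genes lay above every other library, which restates the pattern and is no separate test of it. A male animal for library 8 may account for the pattern, and a sample from outside the group stays open. No biological explanation was tested.

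Library 8 also stood apart from the other 3 wild-type libraries in Cd163 (47.5 FPKM against 4.99 to 7.15), Folr2 (180.9 against 15.0 to 25.5), Lyve1 (61.8 against 5.51 to 7.21), Mrc1 (445.0 against 100.5 to 156), Col1a2 (77.2 against 3.79 to 6.12), Col3a1 (72.7 against 7.13 to 8.38), Pdgfra (13.01 against at most 2.34), Postn (56.4 against 1.70 to 4.24) and Fscn1 (10.7 against 0.684 to 2.11). Labelled knockout library 5 had the lowest relative depth, 0.22 against 0.7 to 0.78 in the other 3 of its group, and 11138 genes listed at 0 against 9030 to 9294. Abi3 was 17.3 FPKM in labelled knockout library 5 against 14.9 in the other 3, and Parp11 was 9.42 there against 11.2 to 11.4. Kdr was 5.19 FPKM in labelled knockout library 6 against 3.25 to 3.36. Il1rl2 was 10.2 FPKM in wild-type library 7 against 6.77 to 7.15. Eif2s3y was 0.0642 FPKM in labelled knockout library 6 and listed at 0 in the other 3.

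The IL4 response differed between genotypes, by a test of the difference itself, for 5 genes named in the report, Arg1 at both times. The difference was −1.39 for Arg1 at 10 h (limma, adjusted p = 0.0113). At 24 h it was −1.59 for Arg1, −1.69 for Timp1, −1.36 for F10, −2.21 for Ear3 and 1.38 for Ednrb (adjusted p at most 0.00363). The Arg1 call at 10 h was lost without 6 of the 8 libraries in turn, with an adjusted p up to 0.0940 (without replicate 1 of the untreated labelled knockout).

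Other splits of the libraries were counted for the main results. In TAM 2 of the 35 splits into 4 and 4 gave at least the 10 genes of the real split, so chance is not excluded. The highest other, with 29, was libraries 1 to 4 against 5 to 8, which points to a structure of the samples, and 28 splits gave 0. For gene lists 11 of 35 splits gave at least the 8 of the real split (highest other 12), so chance is not excluded. For the lower values of genes repressed by IL4, 1 of 35 splits, the real one, had a p as small (smallest other 0.00285), under 5% of all splits. Only 18 splits keep 2 libraries of each of the sets 1 to 4 and 5 to 8 on each side, too few for a share under 0.05. Among these the real split stood alone for the IL4-repressed genes (smallest other p 0.00424) and for genes (10, highest other 1), and 6 gave at least 8 lists (highest other 12). In BMDM averaged over times, 1 of 100 splits drawn from 108, the real one, gave at least 1045 genes (highest other 190). A random split of the libraries is thus argued against. These splits treat the libraries as independent. Differences between animals or cultures that go with the label are not covered. For the gene lists of that average 16 of 100 splits gave at least 6 (highest other 8), so chance is not excluded.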

How the results depend on the processing

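The TAM sets of libraries 1 to 4 and 5 to 8, the averaging of labelled knockout libraries 3 and 4, and leaving out short RNA genes were tests chosen only after the data were seen. No named gene changed sign with a call. Over all alternatives, gene results kept their side of the threshold in 2175 cases, lost the call in 156 and gained it in 26, and list results in 595, 86 and 15. The sign changed in 36 gene and 6 list cases without a call that reversed. The cause was not tested unless stated.

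With no filter, calls numbered 459 for labelled knockout against wild type at 0 h, 31 and 96 for the interactions at 10 and 24 h and 6 in TAM. Requiring 1 FPKM in every library, which tests fewer genes, gave 138 at 0 h, 149 at 10 h, 645 averaged, and 2 and 8 for the interactions, and a correlation between 0 and 10 h of 0.52. Using only the libraries compared leaves fewer degrees of freedom and takes the spread from those libraries alone. It gave 3362 and 2908 for IL4 at 10 and 24 h in wild type and 14 for the interaction at 24 h. Between genotypes it gave 118 and 18 at 0 and 24 h. Counts rose to 427 between genotypes at 10 h and to 5532 and 5714 for IL4 in the labelled knockout. BMDM replicates differed most in wild type at 0 and 24 h (SD of the log2 difference 0.266 and 0.28, against 0.132 to 0.173). The joint fit pools these spreads. For the average, using only the libraries compared equals the reported fit. Median-of-ratios scaling gave 1208 between genotypes at 24 h, 157 for the interaction at 24 h, 6 in TAM (1 higher, 5 lower), 5 lists at 0 h and a median of 0.06 for the IL4-induced genes in TAM, which then passed. Quantile normalization gave 115 for the interaction at 24 h and 6 in TAM (1 higher, 5 lower), a pseudocount of 0.1 gave 17 for that interaction, and no trend gave 6 in TAM. With an estimated correlation 0 lists passed in each of the 11 comparisons (camera).

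In TAM array weights gave 2055 genes (1509 higher, 546 lower). The weights were highest for labelled knockout libraries 3 (4.38) and 4 (3.05) and wild-type library 1 (3.10). They were lowest for wild-type library 8 (0.24) and labelled knockout libraries 5 (0.33) and 6 (0.46). The sets as a block gave 31, and 135 without wild-type library 8. Averaging labelled knockout libraries 3 and 4 gave 1, libraries 1 to 4 alone 1 and libraries 5 to 8 alone 134.

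Without single libraries, calls ranged over 2859 to 5007 and 2708 to 2832 for IL4 at 10 h in wild type and labelled knockout. Between genotypes they ranged over 98 to 1392, 94 to 126, 156 to 1257 and 613 to 1789 at 0, 10 and 24 h and averaged, over 5 to 62 and 11 to 1169 for the interactions, and over 1 to 23 in TAM. The median of IL4-induced genes in TAM ranged over 0.14 to 0.22. BMDM list calls were not recomputed without single libraries, and leaving out TAM libraries does not apply to the IL4 lists in BMDM. With replicate number as a replicate block, 941 genes passed averaged over times (660 higher, 281 lower), and deviations of libraries with equal numbers correlated by −0.14 to 0.15 over 15 pairs (median 0.05). Depth in counts is unknown, and labelled knockout library 5, at a relative depth of 0.22, limits low genes in TAM.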

Other observations

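The test on the neighbours of Tet2 was chosen before its result was seen, and the values in the next paragraph were chosen only after they were seen.

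In BMDM labelled knockout, IL4 moved further lists that the report leaves out. In all 4 lists rose and 1 fell at 10 h, and 7 rose and 3 fell at 24 h (camera). Not all of them are named in the text. At 10 h 5 of 9 MHC class II genes rose (camera, adjusted p = 0.0143) and 8 of 17 complement and macrophage identity genes fell with 2 rising (0.00707), both with an adjusted p = 0.772 with an estimated correlation. At 24 h 12 of 24 inflammatory genes fell and 6 rose (adjusted p = 0.0344; 0.0619 with median-of-ratios scaling; adjusted p = 0.490 with an estimated correlation), and 16 of 21 glycolysis and hypoxia genes rose and 2 fell (0.00892; adjusted p = 0.490 with an estimated correlation). The BMDM libraries of both genotypes carried a male pattern, with Ddx3y at 18.4 to 28.0 FPKM and Xist at 0 to 0.00721 FPKM. Folr2, Lyve1 and Mrc1, high in wild-type TAM library 8, are genes of resident macrophages.

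A hypothesis was that variants carried along from the strain in which Tet2 was targeted could account for genes that differ between genotypes in BMDM. Of the 50 tested genes on each side of Tet2, 17 of 100 were called averaged over times (17%, exact 95% interval 10.2% to 25.8%) against 9.92% of 10352 other genes (Fisher's exact test, two-sided, p = 0.0276). None of the nearest 10 genes was called (limma). The share was higher near Tet2 but less than 2 times that elsewhere, and its interval includes 2 times, so the hypothesis is neither excluded nor shown. The 1027 called genes elsewhere lie outside the region it covers.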
